A study of Mus musculus with 4 samples.

How the data were processed

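The series holds 4 biotin-labelled RNA samples of NIH/3T3 fibroblasts on 4 Affymetrix mouse arrays of 1 design, 2 of pseudopodia and 2 of cell bodies, grouped and numbered by their titles. Per the labels' protocols, cells in 10% calf serum medium were starved overnight, plated on Transwell inserts, stimulated with LPA from below, fixed in 0.3% formaldehyde for 10 min and separated by wiping 1 face of the membrane. Crosslinks were reversed at 70 °C for 45 min before total RNA was isolated with Trizol, and RNA was labelled by the standard Affymetrix procedure. Fixation, its reversal and the small amount of material in protrusions could each affect RNA integrity and amplification.

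The deposited value table holds 1 intensity per probe set and array, a MAS5 signal on a linear scale, per the submitters' processing notes. No version, detection call or scaling target is given in the sources used here. Every array had a trimmed mean of 250.0 (2% trimmed at each end), found from the values, so the authors had scaled the arrays to a common target. All values were above 0. MAS5 subtracts mismatch signal, which makes dim probe sets noisy. Scaling each array to 1 target makes every difference relative to the total signal of its fraction, not an amount per cell. The scanner text files deposited with the arrays hold settings only. Per the file headers, all arrays shared 1 chip lot and 1 scanner and were scanned on 2 days, with the replicate 1 arrays of both fractions on 1 day and the replicate 2 arrays on the other.

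Gene names came from the platform annotation: 34958 probe sets had 1 gene symbol, 932 had several and 9211 were unnamed here, and no symbol needed updating against the RefSeq gene table, which served for names and gene types only. Genes are named only from probe sets with 1 symbol. No genome was used, so the position of a probe set within its gene (exon, intron, UTR) was not analysed here.

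Signals were scaled to a trimmed mean of 500 and transformed as log2(signal + 32). A fold change is therefore on the log2(value + pseudocount) scale and understates changes of dim probe sets. Probe sets with a mean at or above the median of all 45037 that are not controls were kept (22519, of which 19352 had 1 gene symbol, from 10962 genes). Pseudopodia and cell bodies were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05 on the adjusted p, without a block. An exact permutation of 2 against 2 arrays cannot give a p below 0.333, so no such test was run on single genes. A rule of size, at least 1.5-fold in each of the 4 array pairs, was set beside the test.

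For 23 gene lists, each gene was represented by its probe set with the highest mean, p was adjusted over genes, and the lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, with adjustment over the lists (camera tests a list against the other genes, fry against no change); a list needed 5 measured members. The lists covered, among others, cytosolic and mitochondrial ribosomal proteins, translation factors, oxidative phosphorylation, recalled protrusion RNAs, actin, focal adhesion, microtubules, Rab GTPases, extracellular matrix, endoplasmic reticulum, cholesterol synthesis, immediate-early genes, long noncoding RNAs, small nucleolar RNA host genes, splicing, proteasome, cell cycle, glycolysis, and markers of blood, epithelium, and adipocytes and muscle. Of the 79 cytosolic ribosomal protein genes only 44 had a probe set with 1 symbol. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

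Named genes are the 15 with the largest rise and the 15 with the largest fall among probe sets past the threshold and of 1 sign in both same-numbered pairs, each by its probe set with the largest change; up to 4 members of each list by the size of the moderated statistic; and 11 genes fixed beforehand. Of the last, Gapdh had no kept probe set with 1 symbol. Genes singled out after their values were seen are marked as such.

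The replicate numbers pair the arrays through the shared scan day. Same-numbered arrays also share an experiment code in the design text, so a block by replicate number, called the scan day below, covers both. Over probe sets, the replicate 2 minus replicate 1 differences in pseudopodia and in cell bodies correlated with r = 0.243, and the differences between fractions in the 2 pairs with r = 0.554; probe sets are not independent replicates. A fit with this number as a block was therefore run beside each result.

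The procedure was tested on simulated data with 200 of 22519 probe sets changed, in 20 runs with the spread drawn from the fitted prior. It found 2.9% of changes of 1 log2 unit and 50.6% of changes of 2 log2 units. The estimate had the right sign in 99.5% of all changed probe sets, and 4.23% of calls were false. Of 20 runs without any change, 2 gave a call. The data gave 990 calls, more than the 200 probe sets changed here, so their Benjamini-Hochberg cut-off on p was more lenient. The shares found therefore do not carry over to the data. A list of 50 genes shifted by 0.4 was found in 20 of 20 runs with the preset and in 15 of 20 with the estimated correlation, and an unshifted list was called in 1. In these runs p was adjusted over 2 lists, against 23 in the data, so these rates do not carry over either. Simulated probe sets were independent of each other. In the data the estimated correlation ranged from -0.20 (adipocyte and muscle markers) to 0.50 (cytosolic ribosomal proteins). The runs therefore do not give the rate of false calls for lists with correlated members.

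Alternatives were pseudocounts of 1 and 128, quantile normalization, median centring, no filter and a filter at the 75th percentile, the block, no variance trend, only probe sets without the suffixes that mark shared or similar transcripts (called probe sets for a single transcript), the mean over the probe sets of a gene, 2-fold in the rule of size, and leaving out each array in turn. Scaling on 9 hybridization control probe sets, lists without the recalled RNAs, and probe sets for a single transcript in the lists and the rule of size were added after seeing the data. Tables, bootstrap intervals (10000 draws, 95%) and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.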

Results

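RNA from the pseudopodia and from the cell bodies of migrating NIH/3T3 cells, a mouse fibroblast line, was measured on Affymetrix mouse expression arrays. Serum-starved cells spread for 2 h on a porous, fibronectin-coated membrane of 24 mm diameter. Lysophosphatidic acid (LPA), a serum phospholipid that stimulates cell migration, was then placed below the membrane at 150 ng/ml for 1 h, and the cells extended protrusions through the pores towards it. After light fixation the protrusions were collected from the underside and the cell bodies from the upper side. The data comprise 4 arrays, 2 of pseudopodia and 2 of cell bodies, from samples described as independent. The labels do not describe how the cultures were separated, so the p-values measure the spread between these samples only. Each array gave a MAS5 signal for 45101 probe sets, of which 64 were controls. The median signal was 29.8 and 33.2 on the cell body arrays and 31.0 and 33.3 on the pseudopodia arrays, and the precision was limited by the number of arrays. The comparison asks which RNAs are relatively enriched in, or depleted from, the protrusions. Unstimulated cells were not analysed here. Differences are given as log2 of pseudopodia over cell body ± SE of the limma fit, with n = 2 arrays per group throughout.

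The RNAs of Kif1c, a kinesin motor, Pkp4, a plakophilin of cell junctions, and Rab13, a small GTPase of vesicle traffic, were about 4 times as abundant in pseudopodia as in cell bodies relative to total signal. Their folds were 4.40, 4.18 and 3.98. In the other direction, Neat1, a long noncoding RNA retained in the nucleus, differed by -2.17 ± 0.21 (adjusted p = 0.00891 over genes). A dimmer probe set of Neat1 stood at -0.83 and did not pass. The RNAs of P4ha2 and Plod1, enzymes that hydroxylate collagen, differed by -1.66 ± 0.19 and -1.50 ± 0.19 (adjusted p = 0.0108 and 0.0144 over genes). Of 22519 probe sets kept, 990 passed the threshold, 243 higher and 747 lower in pseudopodia, belonging to 175 and 497 genes. The median fold was 2.14 among the higher and 2.75 among the lower probe sets, and all 990 had the same sign in both same-numbered pairs of arrays. Passing the test on 2 against 2 arrays nearly requires that shared sign, so it is not independent evidence. With the scan day, which the replicate number marks, as a block, 1541 probe sets were higher and 2546 lower, and all 990 remained. That fit leaves 1 residual degree of freedom, against 16.8 from the fitted prior (2 and 5.56 without the block). Its p-values, here and in the gene lists below, therefore rest mostly on a shared estimate of spread. They are not independent support. At least 1.5-fold apart in each of the 4 array pairs were 629 higher and 1769 lower probe sets. The arrays of the 2 fractions did not overlap in 53.0% of the probe sets, where chance gives 33.3%. Within the replicate 1 pair alone, 2583 probe sets were at least 1.5-fold higher and 4335 lower, and within the replicate 2 pair 2934 and 4494.

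The count of 990 rested on the variance model. Without the variance trend limma called 0 probe sets (4487 at an unadjusted p under 0.05, against 4956 with the trend). Leaving out an array leaves a lone array in its fraction, and the spread then comes from the other fraction only. Counts from such fits therefore do not show which arrays the 990 calls rest on. Without the filter on dim probe sets 176 passed. The split between directions depended on the scaling, with 385 higher and 472 lower after median centring, and 71 higher and 1869 lower after scaling on the hybridization controls, a setting chosen after seeing the data. These scalings moved the median of all probe sets from -0.03 to 0.13 and -0.34. The values of gene groups are therefore given relative to the median gene, which stood at 0.01 in the fit reported here. Beside every group stands a difference in a sign of RNA integrity: the beta-actin 3' to 5' control ratio was 1.14 times as high in pseudopodia as in cell bodies in replicate 1 and 1.81 times in replicate 2. For Gapdh the same ratio was 1.05 and 1.06 times as high.

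The 15 genes with the largest rise in pseudopodia differed by 1.84 to 2.51, with adjusted p between 0.0109 and 0.0327. The largest rise was that of 5730409E04Rik, at 2.51 ± 0.22, with deposited signals of 388.8 and 344.7 in cell bodies and 1885.9 and 2461.7 in pseudopodia. Kif1c differed by 2.14 ± 0.22, with signals of 1149.0 and 1378.7 against 4661.3 and 6704.9, although its 3 dimmer probe sets did not pass, at 0.86, 0.22 and 0.41. Sh3pxd2a, a scaffold protein of podosomes, differed by 1.87 ± 0.20, and by -0.07 on a dimmer probe set. Trp53inp2, a regulator of autophagy, also stood at 1.87 on its brightest probe set, with an SE of 0.17, but another of its probe sets was lower. Trak2, an adaptor that links mitochondria to kinesin, was higher by 1.98 ± 0.24. Cyb5r3, a cytochrome b5 reductase, was higher on all 3 of its probe sets, at 2.39, 1.74 and 1.61. Kank2, an adaptor at cell adhesions, was higher on both of its probe sets (2.36 and 1.85), as was Ddr2, a receptor for collagen (1.89 and 1.54). Dynll2, a dynein light chain, was higher by 1.94 ± 0.26 on 1 probe set while its brightest probe set stood at 0.10. The remaining genes were Trim12c, Nbeal1, Naa50, which encodes an N-terminal acetyltransferase, and Cplx2, a complexin, at 2.31, 2.18, 1.85 and 1.84. The brightest probe sets of Nbeal1 and Naa50 did not pass (both 1.55, adjusted p = 0.0715 and 0.0681), and others stood at -1.17 in Nbeal1 and 0.04 in Naa50.

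In the gene groups that follow, fixed before the data were examined, each gene stands by its brightest probe set and p is adjusted over 10962 genes. Of 10 protrusion RNAs recalled from this study and its follow-ups, 7 were higher (Kif1c, Pkp4, Rab13, Trak2, Kank2, Cyb5r3 and Ddr2) and none was lower, with a median 1.78 above the median gene (1.79 and 1.72 in the 2 replicate pairs). This list was chosen partly on these samples, so its count, also 7 when adjusted over the list alone, is not independent evidence. The exceptions were Net1 at 0.70 ± 0.77 (1.57 in replicate 1 and -0.17 in replicate 2), Dynll2 at 0.10 and Inpp1 at 0.01, each on its brightest probe set. The list was called by camera with a preset correlation (adjusted p = 2.75e-09), but not with an estimated correlation (adjusted p = 0.262 with an estimated correlation). Its adjusted p by fry, which tests a list against no change and not against other genes, was 0.0268, and 0.0850 with the scan day as a block.

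Among 52 measured members of the list of microtubules, kinesins and dynein, 8 were higher and none lower, or 12 higher and 1 lower when adjusted over the list alone. Besides Kif1c and Trak2 these included Kif5b, the heavy chain of conventional kinesin (1.37 ± 0.20, adjusted p = 0.0186), Dynlt3, a dynein light chain (1.24 ± 0.20, adjusted p = 0.0254), and Apc, a tumour suppressor that binds microtubule plus ends (1.10 ± 0.21, adjusted p = 0.0300). Dimmer probe sets of Kif5b stood at 0.43, 0.15, 1.34 and 0.85. The list stood 0.17 above the median gene (0.20 in each replicate pair; camera adjusted p = 0.00076; adjusted p = 0.350 with an estimated correlation). Without the recalled protrusion RNAs, an alternative chosen after seeing the data, it stood 0.13 above with 6 members higher (camera adjusted p = 0.00532, and 0.350 with an estimated correlation). Of 58 measured Rab GTPases and trafficking proteins, 3 were higher, namely Rab13, Arf3 (0.89 ± 0.20) and Gdi2, which extracts Rab proteins from membranes (0.87 ± 0.15), with the same count over the list alone. Dimmer probe sets of Arf3 did not pass, at 0.15, -0.06, 0.52 and 0.08. Those of Gdi2 stood at 0.76, 0.65, 0.44, -0.51 and -1.11. Rab5b, of early endosomes, was lower (-1.91 ± 0.23, adjusted p = 0.0108). This list stood 0.22 above the median gene (0.21 and 0.05 in the replicate pairs; camera adjusted p = 0.00522; adjusted p = 0.369 with an estimated correlation), and its call ended without pseudopodia replicate 1, at 0.09. After quantile normalization the microtubule list stood at 0.10 and the Rab list at 0.12 (camera adjusted p = 0.0119 and 0.0253, and 0.371 for both with an estimated correlation). Matched on signal, a comparison chosen after seeing the data, they stood at 0.08 and 0.15. On hybridization controls 3 microtubule and 1 Rab list members were higher, and after median centring 9 and 5. With the scan day as a block, 14 microtubule members were higher and 2 lower, and 6 Rab list members were higher and 1 lower.

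**Figure D1:**
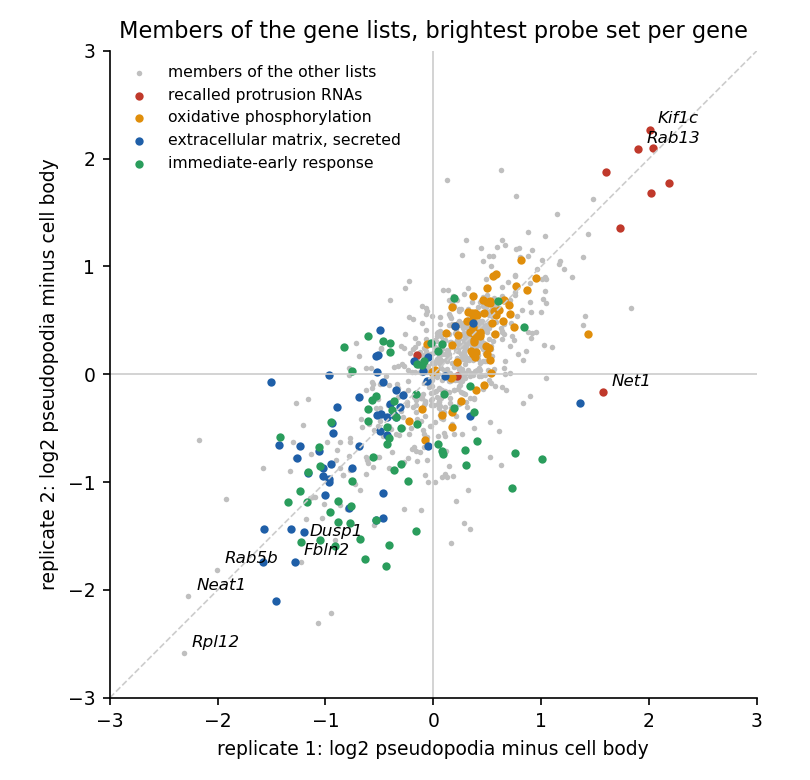
Log2 difference between pseudopodia and cell body for the members of the gene lists, with the replicate 1 pair on the x axis and the replicate 2 pair on the y axis; each point is 1 gene by its brightest probe set, 4 lists are coloured and the dashed line marks equal values. Kif1c and Rab13 lie near 2 in both pairs, Neat1 near -2, and Net1 at 1.57 in replicate 1 and -0.17 in replicate 2.

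The RNAs of secreted and extracellular matrix proteins stood lower in pseudopodia as a list, although most members did not pass. Of 55 measured, 17 were lower and none higher, with 25 lower and 1 higher when adjusted over the list alone. The list stood at -0.52 relative to the median gene (-0.55 and -0.46 in the replicate pairs), and 5 of its members had positive values. Examples were P4ha2 and Plod1, P4ha1 (-1.38 ± 0.19, adjusted p = 0.0165), which also hydroxylates collagen, and Fbln2, a glycoprotein of elastic fibres and basement membranes (-1.51 ± 0.17, adjusted p = 0.0108). The camera adjusted p was 4.20e-12 (adjusted p = 0.262 with an estimated correlation), and that of fry, against no change, was 0.0297, or 0.136 with the scan day as a block. After quantile normalization the list stood at -0.79 with 20 lower, after median centring 8 were lower, and on hybridization controls 26 (43 over the list alone).

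RNAs of the endoplasmic reticulum machinery for protein translocation and folding stood at -0.39 (-0.45 and -0.28 in the replicate pairs), with 10 of 50 lower and 1 higher, or 15 and 3 adjusted over the list alone. These included Pdia6, a disulfide isomerase (-1.26 ± 0.24, adjusted p = 0.0300), Ero1a, an oxidase of the same pathway (-1.18 ± 0.21, adjusted p = 0.0277), Herpud1, of the degradation of misfolded proteins (-1.14 ± 0.20, adjusted p = 0.0269), and Rpn2, a subunit of the oligosaccharyltransferase (-1.12 ± 0.19, adjusted p = 0.0261). Its camera adjusted p was 7.57e-06 (adjusted p = 0.350 with an estimated correlation). Cholesterol synthesis, whose later enzymes are membrane proteins of the same organelle, stood at -0.42 (-0.26 and -0.49 in the replicate pairs), with 4 of 20 lower and none higher, or 8 lower over the list alone. The 4 were Msmo1 (-1.11 ± 0.19), Sc5d (-1.04 ± 0.20), Sqle (-0.77 ± 0.17) and Cyp51 (-0.71 ± 0.16), with adjusted p from 0.0269 to 0.0469. Its camera adjusted p was 0.000304 (adjusted p = 0.369 with an estimated correlation). A dimmer probe set of Sc5d stood at 0.31 and did not pass. With the scan day as a block, 31 extracellular matrix members were lower and 1 higher, 20 endoplasmic reticulum members lower and 3 higher, and 9 cholesterol members lower. After median centring 5 endoplasmic reticulum and 2 cholesterol members were lower, and on hybridization controls 14 and 7 (28 and 12 over the list alone).

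Immediate-early genes, whose RNAs are made within minutes of serum or LPA stimulation, also stood lower in pseudopodia as a list, although most members did not pass. Of 68 measured, 10 were lower and none higher, or 12 lower when adjusted over the list alone. Dusp1, a phosphatase of MAP kinases, differed by -1.39 ± 0.19 (adjusted p = 0.0165), and the AP-1 subunits Jun and Fosb by -1.18 ± 0.18 (adjusted p = 0.0228) and -1.25 ± 0.24 (adjusted p = 0.0317). Trib1, a pseudokinase, differed by -1.30 ± 0.27 (adjusted p = 0.0363), and by 0.23 on a dimmer probe set that did not pass. The list stood at -0.40 relative to the median gene, with -0.43 and -0.64 in the replicate pairs. Its camera adjusted p was 2.61e-06 (adjusted p = 0.40 with an estimated correlation). With the scan day as a block 28 were lower and 3 higher. The count of 10 fell to 3 after median centring and 4 after quantile normalization, and was 15 (27 over the list alone) on hybridization controls. Leaving out 1 array at a time moved the list between -0.22 and -0.78, the former without cell body replicate 2 and the latter without pseudopodia replicate 2, with the call kept.

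The RNAs of the respiratory chain were shifted towards pseudopodia. Of 69 nuclear-encoded members measured, 63 had positive values and 6 passed as higher with none lower, or 17 higher when adjusted over the list alone. The highest by test were Uqcrb, of complex III (0.83 ± 0.13, adjusted p = 0.0228), Cycs, cytochrome c (0.92 ± 0.16, adjusted p = 0.0274), Atp5j, of the ATP synthase (0.79 ± 0.16, adjusted p = 0.0330), and Ndufa5, of complex I (0.93 ± 0.21, adjusted p = 0.0414). The list stood 0.38 above the median gene (0.37 and 0.38 in the replicate pairs; camera adjusted p = 6.09e-12; adjusted p = 0.369 with an estimated correlation). Mitochondrial ribosomal proteins stood 0.26 above it in both replicate pairs and in the mean of both, with 3 of 74 higher and none lower in either count, namely Mrpl52 (1.10 ± 0.20), Mrpl32 (0.94 ± 0.19) and Mrps15 (0.94 ± 0.21). Their camera adjusted p was 3.81e-06 (adjusted p = 0.350 with an estimated correlation). Dimmer probe sets of Mrps15 stood at 1.18 and -1.08. Quantile normalization brought the respiratory chain list to 0.11 and the mitochondrial ribosomal list to 0.15, with both still called. The respiratory chain counts depended on the scaling: quantile normalization left 50 positive values and 4 higher, also over the list alone, hybridization controls 42 and 1 (0 over the list alone), and median centring gave 65 and 8 (36 over the list alone). Mitochondrial ribosomal members higher numbered 3, 1 and 6 in the same order (2, 0 and 14 over the list alone). With the scan day as a block, 38 respiratory chain and 17 mitochondrial ribosomal members were higher.

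Cytosolic ribosomal proteins stood 0.34 above the median gene (0.39 and 0.30 in the replicate pairs; camera adjusted p = 6.09e-12; adjusted p = 0.369 with an estimated correlation) and translation factors 0.33 (0.35 and 0.29; camera adjusted p = 2.90e-06; adjusted p = 0.350 with an estimated correlation), but after quantile normalization both stood slightly below it, at -0.06 and -0.05, and neither was called. The call on the ribosomal list also ended when only probe sets for a single transcript were used, an alternative added after seeing the data (20 genes, median 0.30 but mean difference -0.14, 12 with positive values, 5 higher and 4 lower, or 10 and 5 over the list alone; camera adjusted p = 0.146). Of 43 ribosomal protein genes measured, 41 had positive values and 3 were higher, or 24 when adjusted over the list alone: Rps6 (0.97 ± 0.18), Rpl37 (0.96 ± 0.17) and Rpl14 (0.84 ± 0.19). After quantile normalization 25 of the 43 had positive values and 4 were higher over the list alone, and on hybridization controls 22 and 0. Of the 2 genes with negative values, 1 passed, Rpl12, at -2.45 ± 0.29 (adjusted p = 0.0108), the single member lower in either count, by the only probe set kept for it. That probe set had signals of 322.1 and 517.8 in cell bodies, against 1718.5 and 1983.8 for Rps6. Whether it reads the main Rpl12 transcript was not analysed here. Of 33 translation factors 2 were higher, or 4 over the list alone, both subunits of initiation factor eIF3: Eif3a (1.11 ± 0.19) and Eif3e (0.97 ± 0.15). Dimmer probe sets stood at 1.26 and -1.10 in Eif3a and at 0.67 and 1.04 in Eif3e. The list of actin and Arp2/3 machinery stood 0.31 above the median gene (0.28 and 0.35 in the replicate pairs; camera adjusted p = 6.05e-06; adjusted p = 0.350 with an estimated correlation). Of its 52 measured members, Palld, an actin-bundling protein, was higher (1.32 ± 0.25, adjusted p = 0.0307) and Myl6, a myosin light chain, lower (-1.03 ± 0.24, adjusted p = 0.0463), with 8 higher and 2 lower over the list alone. Myl6 also stood by the only probe set kept for it, with signals of 371.9 and 367.8 in cell bodies. After quantile normalization the actin list stood at 0.13 (camera adjusted p = 0.0360). On hybridization controls no translation factor and no actin list member was higher over the list alone, and after median centring 13 and 18 were. Actb, beta-actin, stood at 0.21 ± 0.13 (adjusted p = 0.387), and at -0.13 after quantile normalization and -0.14 after scaling on the hybridization controls. With the scan day as a block, 29 ribosomal protein genes were higher and 1 lower, 15 translation factors were higher, and 19 actin list members were higher and 3 lower.

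**Figure D2:**
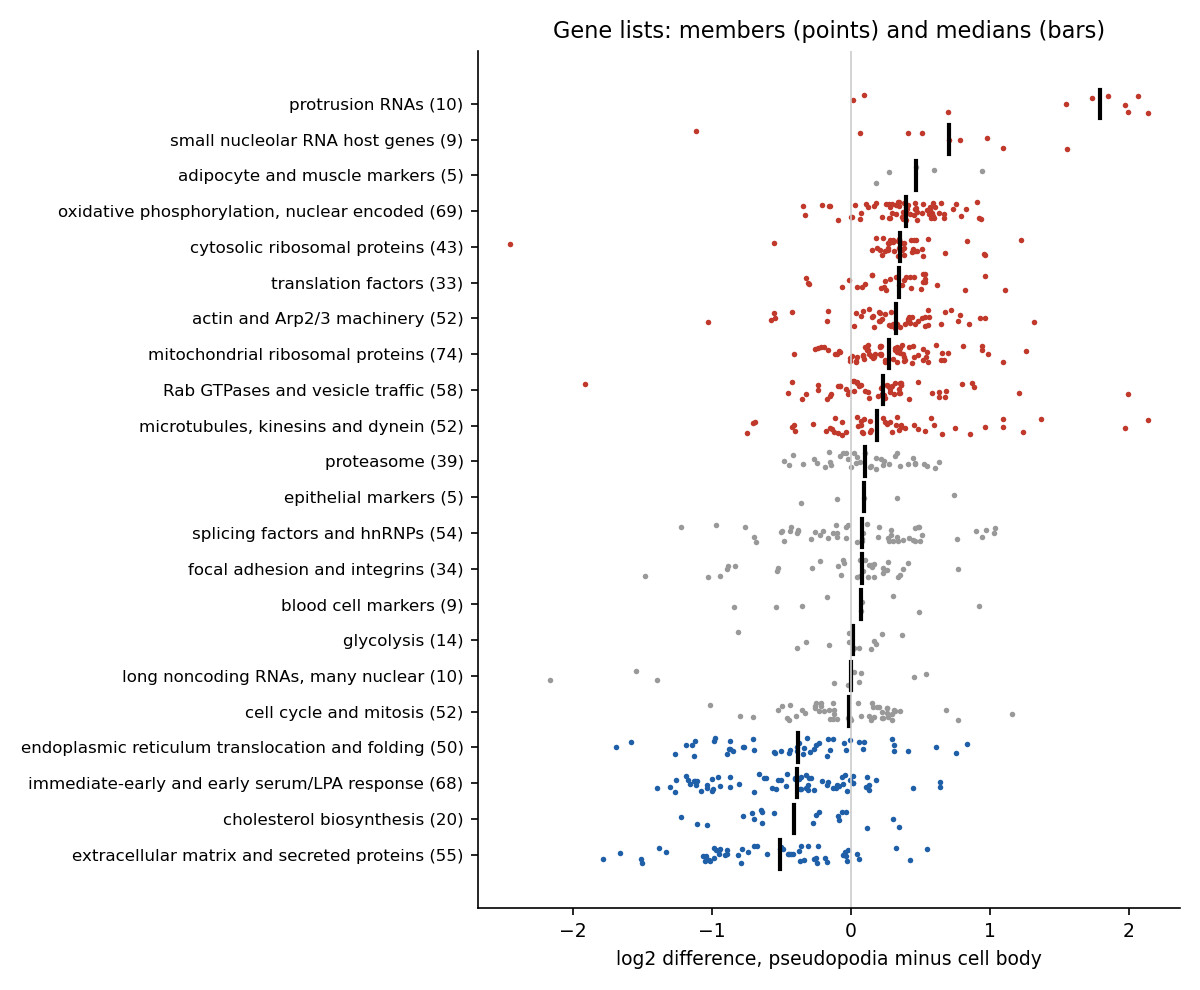
Log2 difference between pseudopodia and cell body (x axis) for each measured member of the gene lists (points, brightest probe set per gene, number of members in parentheses) with the median of each list as a bar; red lists were called higher and blue lists lower by camera with a preset correlation, and grey lists were not called. Recalled protrusion RNAs stand at the top with a median 1.78 above the median gene, and extracellular matrix at the bottom with -0.52; cytosolic ribosomal proteins and translation factors fall slightly below the median gene, at -0.06 and -0.05, after quantile normalization.

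Bright probe sets at large stood higher in pseudopodia. In 10 groups by mean signal, the median difference was 0.24 in the brightest group and between -0.07 and -0.10 in groups 3 to 8, and after quantile normalization it lay between -0.02 and 0.07 in all of them.

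**Figure D3:**
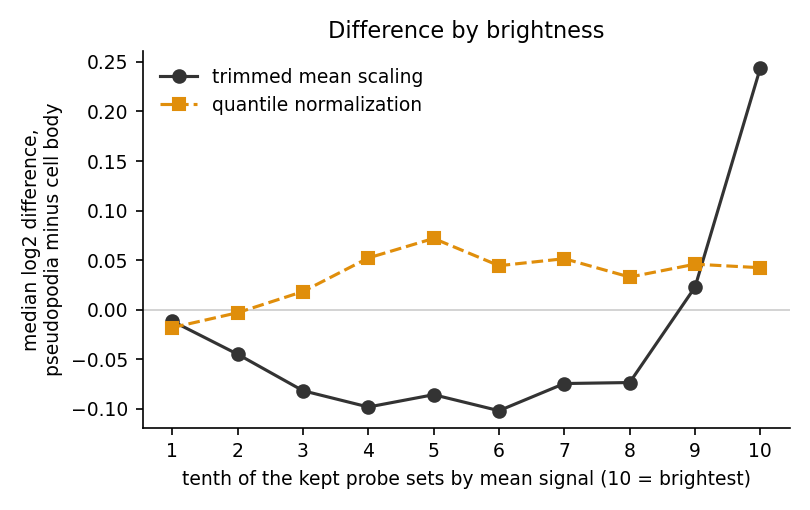
Median log2 difference between pseudopodia and cell body (y axis) of kept probe sets in 10 groups of equal size by mean signal (x axis), after trimmed mean scaling and after quantile normalization. The brightest group stands at 0.24 with trimmed mean scaling and at 0.04 with quantile normalization.

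The 15 genes with the largest fall in pseudopodia differed by -2.59 to -3.43, with adjusted p between 0.0109 and 0.0348. Most of them were on probe sets dim in pseudopodia. In 11 of the 15 at least 1 pseudopodia signal lay under the median of its array, and in 7 both did, so the pseudocount limits the size of these differences and sets their order. With a pseudocount of 1 in place of 32, Gcn1, regulator of an eIF2 kinase, differed by -4.90 and Zmiz1, a transcriptional coactivator, by -3.98. In the fit reported here Zmiz1 had signals of 451.0 and 509.7 in cell bodies and 24.4 and 36.4 in pseudopodia, a difference of -3.43 ± 0.26. Myo9b, an unconventional myosin, differed by -3.32 ± 0.37, Nagk, N-acetylglucosamine kinase, by -3.26 ± 0.27 and Ube2b, a ubiquitin-conjugating enzyme, by -3.23 ± 0.37. The brightest probe sets of these 4 genes did not pass, at -0.10, -0.22, 0.02 and -0.02. The same held for Gcn1, Phb2, Ncaph2, Snhg1, Itprip, Sf3b3 and Nisch, which differed by -2.98, -2.91, -2.91, -2.87, -2.70, -2.65 and -2.61 on the named probe set and by -0.73, 0.54, -0.11, 0.41, -1.27, -0.50 and 0.15 on the brightest. In Man2b1, lysosomal alpha-mannosidase, both passed (-2.59 and -1.25), while in Snrnp48 (-2.61) the named probe set was itself the brightest. For H3f3b, a histone H3.3 gene (-2.61), and Ppp1r10 (-2.62) it was the only probe set kept, so no other could be compared. The 2 other probe sets of Snrnp48 stood at 0.32 and 0.35 and did not pass.

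In genes with several kept probe sets, 62.5% of the probe sets were not the brightest of their gene. Among the called ones this held for 297 of 423 lower (70.2%) and 71 of 160 higher probe sets (44.4%). In 7 genes 1 probe set passed as higher and another as lower. They were singled out after their values were seen. Gas5, a host gene of small nucleolar RNAs, had 2 probe sets higher (1.10 and 1.06) and 1 lower (-2.39), and Trp53inp2 had 1 at 1.87 and 1 at -2.55. Probe sets without a single named gene made up 23.3% of the lower, 12.3% of the higher and 14.1% of all kept probe sets. The ratio of 3' to 5' signal of the beta-actin controls, a sign of RNA integrity, differed between the fractions as well, at 1.55 and 1.89 in cell bodies and 1.77 and 3.41 in pseudopodia. For Gapdh it stood at 0.92 and 0.95 in cell bodies and 0.96 and 1.01 in pseudopodia.

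**Figure D4:**
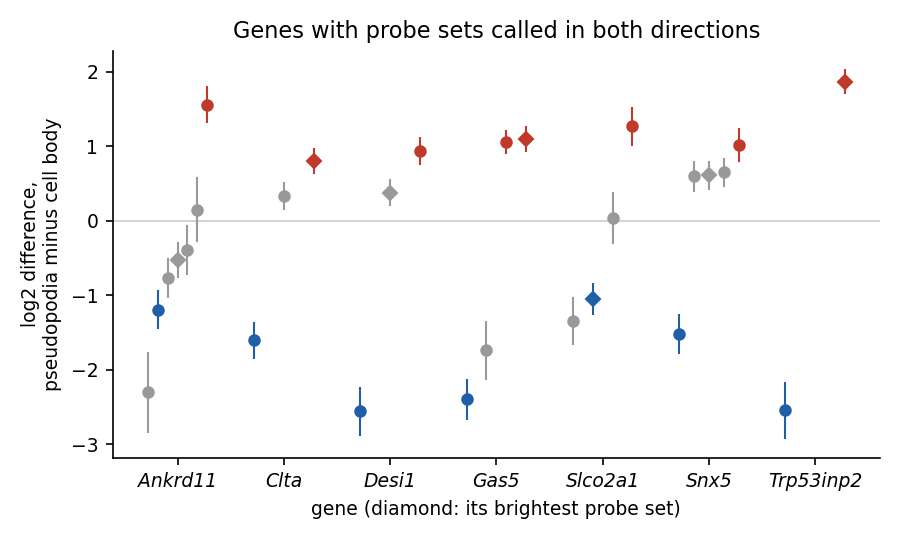
Log2 difference ± SE (bars; n = 2 arrays per group) of every kept probe set of the 7 genes that had probe sets called in both directions, with red called higher, blue called lower, grey not called and a diamond for the brightest probe set of the gene. Gas5 spans 1.10 to -2.39 and Trp53inp2 1.87 to -2.55.

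Among long noncoding RNAs, many of them nuclear, Neat1 and Kcnq1ot1 (-1.54 ± 0.24, adjusted p = 0.0224) were lower and the other 8 measured did not pass, with the same count over the list alone. Malat1, a nuclear RNA of splicing speckles, differed by -1.39 ± 0.48 (adjusted p = 0.130), with -2.17 in replicate 1 and -0.61 in replicate 2, and passed with the scan day as a block (adjusted p = 0.000883 over probe sets, against 0.154 over probe sets without it), where 3 list members were lower. Of its 6 probe sets, 5 had negative values and 1 stood at 0.56. The list's mean was -0.41 and its median 0.00, and it was not called (camera adjusted p = 0.220). Small nucleolar RNA host genes stood 0.69 above the median gene (0.76 and 0.65 in the replicate pairs), with 3 of 9 higher, namely Snhg6 (1.56 ± 0.19), Gas5 (1.10 ± 0.18) and Snhg8 (0.98 ± 0.16), and Snhg3 lower (-1.11 ± 0.23), or 6 higher and 1 lower both over the list alone and with the scan day as a block. The call (camera adjusted p = 0.00076; adjusted p = 0.350 with an estimated correlation) ended when all probe sets of a gene were averaged, at 0.54, and with probe sets for a single transcript only (8 genes, 0.32, camera adjusted p = 0.271).

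Splicing factors and hnRNPs were not shifted as a list (0.07, camera adjusted p = 0.280), although Snrpe, Snrpg and Snrpf, core proteins of small nuclear ribonucleoproteins, were higher (1.03 ± 0.17, 0.76 ± 0.16 and 0.94 ± 0.21) and Rbm39, a splicing regulator, lower (-1.22 ± 0.22). In all, 4 members were higher and 2 lower, also over the list alone, or 9 and 5 with the scan day as a block. Focal adhesion and integrin genes had a median 0.07 above the median gene but a mean difference of -0.10 (camera adjusted p = 0.749), with the integrin subunits Itgb5 (-1.02 ± 0.17, adjusted p = 0.0268) and Itgb1 (-0.88 ± 0.20, adjusted p = 0.0473) lower and none of 34 higher. Over the list alone 4 were lower and 1 higher, and with the block 7 lower and 1 higher.

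The proteasome (0.09, camera adjusted p = 0.161) had no member past the threshold in either count, and 6 of 39 were higher with the block. Cell cycle genes (-0.03, camera adjusted p = 0.744) had 1 of 52 higher in either count, Ccnd2, cyclin D2 (1.16 ± 0.17, adjusted p = 0.020), and 1 higher and 2 lower with the block. Glycolysis (0.00, camera adjusted p = 0.987, mean difference -0.04) had 1 of 14 lower in either count, Slc2a1, the glucose transporter of the plasma membrane (-0.81 ± 0.17, adjusted p = 0.0364). After quantile normalization the glycolysis list was called lower, at -0.25 (camera adjusted p = 0.0152), but not with an estimated correlation (camera adjusted p = 0.371). Markers of other cell types did not pass in either count: blood cells (9 measured, 0.06, mean difference 0.00, camera adjusted p = 0.898), epithelium (5 measured, 0.08, camera adjusted p = 0.719), and adipocytes and muscle (5 measured, 0.46, camera adjusted p = 0.0566). The exception was 1 adipocyte or muscle marker over the list alone, and with the block 1 blood and 1 adipocyte or muscle marker were higher. Lpl, lipoprotein lipase, was the highest of the latter group (0.95 ± 0.25, adjusted p = 0.0639), while a dimmer probe set of it stood at -0.54. None of the 13 lists called with a preset correlation was called with an estimated one. Correlated members alone do not account for this. The estimated correlation was 0.007 for extracellular matrix and -0.099 for recalled protrusion RNAs, both under the preset 0.01. Their unadjusted camera p still went from 1.83e-13 to 0.0160 and from 4.79e-10 to 0.0228. With an estimated correlation, camera uses the 2 residual degrees of freedom of the fit, so the few arrays limit that test. With fry 2 of the 13 passed, recalled protrusion RNAs and extracellular matrix, and none did with the scan day as a block. As fry tests against no change, its count depends on the scaling, with 7 of the 13 after median centring, 2 after quantile normalization and 0 on hybridization controls (lowest adjusted p 0.123). In the fit reported here the other 11 had fry adjusted p from 0.0897 to 0.434, with 0.246 for Rab GTPases and trafficking proteins and 0.434 for immediate-early genes.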

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

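These 3 control signals lie outside the comparison of genes and differed between the fractions; of these only the beta-actin ratio enters the tests given with the other observations. The hybridization controls, labelled transcripts added in equal amount to each sample by the standard procedure, were 1.27 times as bright on the pseudopodia arrays as on the cell body arrays after scaling (1.22 in replicate 1 and 1.33 in replicate 2). The control probe set for the B1 repeat, a short interspersed element found in many transcripts, was 1.54 times as bright (1.66 and 1.42). The beta-actin 3' to 5' ratio was 1.43 times as high in pseudopodia (1.14 and 1.81), where that of Gapdh was 1.05 times as high (1.05 and 1.06). With 2 arrays per group these ratios were not tested.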

How the results depend on the processing

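Scaling on the hybridization controls, the lists without recalled RNAs, and probe sets for a single transcript in the lists and the rule of size were added after seeing the data; the other settings were planned, and a batch other than the replicate number was not found, so none was run. Against 990 calls (243 higher, 747 lower), no filter gave 176 (39, 137), over 45037 probe sets; the block 4087 (1541, 2546), with all 990 kept; no variance trend 0 (0, 0); hybridization controls 1940 (71, 1869); and leaving out 1 array 0 to 3956 (0 to 1304, 0 to 2652), the fit then assuming that the lone array varies like the other fraction. A pseudocount of 1 gave 161 higher, and median centring 385 and 472. The share of higher calls was 24.5%, 44.9% after median centring, 33.5% with the 75th percentile filter and 3.66% on hybridization controls. All other totals were within 1.5 times of 990. Against 629 higher and 1769 lower by the rule of size, 2-fold gave 111 and 604 by construction, the 75th percentile filter 374 and 806, hybridization controls 156 and 3324, and leaving out 1 array 1356 to 1817 and 2411 to 3518; higher ones alone moved with a higher pseudocount (363), probe sets for a single transcript (372), median centring (1161), no filter (1371) and the replicate block (1035). Estimated correlations ended all 13 list calls (0 left); the others left 11 to 16, 11 with probe sets for a single transcript only, and the block changed no camera call. Calls that ended were ribosomal proteins and translation factors (quantile), ribosomal proteins and small nucleolar RNA host genes (probe sets for a single transcript), the latter (mean over probe sets) and Rab (without pseudopodia replicate 1). Calls gained were adipocyte and muscle markers (quantile, no trend, hybridization controls, without cell body replicate 2), glycolysis (quantile), long noncoding RNAs (75th percentile, without cell body replicate 1 or pseudopodia replicate 2), proteasome (without cell body replicate 2 or pseudopodia replicate 2) and splicing (without pseudopodia replicate 2). Relative to the median gene, list values turned sign as follows. Quantile normalization gave cytosolic ribosomal proteins -0.0634, translation factors -0.0506, focal adhesion -0.0137, long noncoding RNAs 0.0613, splicing -0.00327 and glycolysis -0.25. Probe sets for a single transcript gave focal adhesion -0.00284, long noncoding RNAs 0.0287, splicing -0.0231, proteasome -0.0282, glycolysis -0.0436 and blood -0.32. No filter gave glycolysis -0.0271, blood -0.0841 and epithelial markers -0.0169. The mean over probe sets gave focal adhesion -0.13, long noncoding RNAs 0.11 and epithelial markers -0.0534; the higher pseudocount gave epithelial markers -0.0163, and hybridization controls glycolysis -0.00916. Without 1 array, focal adhesion ranged from -0.0224 to 0.0768, long noncoding RNAs from -0.13 to 0.16, splicing from -0.0159 to 0.16, cell cycle from -0.26 to 0.13, glycolysis from -0.0149 to 0.0396, blood from -0.0995 to 0.18 and epithelial markers from -0.0908 to 0.24. Actb turned to -0.13 (quantile) and -0.14 (hybridization controls), and Net1 to -0.58 without pseudopodia replicate 1, against 1.98 (passing) without pseudopodia replicate 2. With middle in place of 5' control probe sets the 3' ratios between fractions were 1.11 for beta-actin, down from 1.43, and 1.05 for Gapdh. The cause was not tested where none is given. Among the lower probe sets, 51 had a pseudopodia signal under the pseudocount.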

Other observations

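Solute carriers, a family not among the lists above and chosen after the lower values of extracellular matrix and endoplasmic reticulum genes had been seen, divided by where their proteins are made. The 164 measured genes of Slc families other than Slc25, whose proteins are synthesised at the endoplasmic reticulum, had a median difference of -0.58. Of these, 79.3% had negative values, and 20 passed as lower and 0 as higher in the fit over probe sets. The 36 measured genes of the Slc25 family, carriers of the mitochondrial inner membrane made in the cytosol, had a median of -0.05, and 0 passed in either direction. The medians differed by -0.52 (two-sided permutation p = 0.00026 over genes, which are not independent replicates), by -0.61 and -0.40 in the replicate pairs, and by -0.52 after quantile normalization. Slc2a1, of the plasma membrane, stood at -0.81.

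By annotated gene type, 11 of 363 kept probe sets of long noncoding RNAs were higher and 9 lower, against 202 and 559 of 18864 for protein-coding genes; the difference was not tested. The other splits of the 4 arrays into pairs gave 0 calls each, with 651 probe sets at an unadjusted p under 0.05 when replicate numbers were compared and 106 when the pairs were crossed, against 990 calls and 4956; with 3 splits the smallest share that can be reached is 0.333.

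Of the tests below, the matching of gene lists on signal and the test on nuclear RNAs were chosen only after the results were seen; the others were set before their values were computed.

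RNAs of extracellular matrix and endoplasmic reticulum proteins stood lower in pseudopodia as lists. Of their members, 17 of 55 and 10 of 50 passed as lower, and 1 of the endoplasmic reticulum list as higher. Neither list was called with an estimated correlation (camera adjusted p = 0.262 and 0.350). The tables argue against a scaling that depends on brightness as the whole cause, since both lists together differed by -0.607 from other genes of equal signal (95% bootstrap interval -0.768 to -0.487, 105 genes). A 3' bias of pseudopodia RNA stays open, because replicate 2, in which the beta-actin ratio differed more, minus replicate 1 gave 0.0266 (-0.0289 to 0.127), which excludes neither sign. This order of the replicates rests on beta-actin alone, since the Gapdh ratio was 1.05 and 1.06 times as high in pseudopodia in replicates 1 and 2. A candidate explanation is that RNAs translated at the endoplasmic reticulum, an organelle with its main mass around the nucleus, stay as a class in the cell body; the solute carriers, predicted to differ below 0, differed by -0.522 (-0.727 to -0.366). This is a hypothesis, found and tested on the same arrays.

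Cytosolic ribosomal proteins, translation factors and the respiratory chain stood higher as lists. Of their members, 3 of 43, 2 of 33 and 6 of 69 passed as higher, and Rpl12 passed as lower on the only probe set kept for it. None of these lists was called with an estimated correlation (camera adjusted p = 0.369, 0.350 and 0.369). Bright probe sets at large also stood higher, with a median of 0.24 in the brightest of 10 groups. The first 2 lists together stood only 0.0254 above other genes of equal signal (-0.0140 to 0.0691, 76 genes), as a scaling or saturation effect that depends on brightness would give, and quantile normalization turned them to -0.06 and -0.05. A true enrichment of abundant cytosolic RNAs would look alike, and stays open as untested. The respiratory chain list stood 0.136 above genes of equal signal (0.0761 to 0.244, 69 genes), which such an effect alone does not account for. No technical cause was tested for that remainder.

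In genes with several probe sets, the dimmer ones lay lower in pseudopodia than the brightest, by a median of -0.12 over 8390 probe sets and by more than 1 log2 unit in 696, against 248 that lay as far above. Brightness alone is argued against, since the dimmer probe sets differed by -0.0734 from the brightest probe sets of equal signal (-0.0909 to -0.0591). The small common shift was more negative in replicate 2 by -0.0753 (-0.0930 to -0.0558), the direction predicted for a 3' bias. This compares 1 pair of arrays with 1 other pair, ordered by the beta-actin ratio alone. Its interval covers the spread over probe sets, not between replicates, so a 3' bias stays open for this shift. Among the 696 the replicates did not differ measurably, at 0.0284 (-0.0459 to 0.128), and there too it stays open. Nuclear RNA such as unspliced transcripts stays open: the 8 probe sets of Malat1 and Neat1 had a median of -0.929, between the bounds set for and against it, and Neat1 still had signals of 687.2 and 927.2 in pseudopodia. Probe positions were not analysed here, so these explanations cannot be told apart for the 696.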
